A study of Mus musculus with 10 samples.

How the data were processed

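Bulk RNA sequencing covered 10 libraries, 5 from wild-type and 5 from Padi4-knockout kidneys, all after 10 days of ureteral obstruction. Group and replicate number were taken from the sample titles. Per the labels' protocols, RNA was extracted with TRIzol and made into mRNA libraries. Per the submitters' processing notes, reads were aligned with HISAT2 2.0.5. The read counter, its handling of strand and of reads with several alignments, the annotation and the genome build are not given in the sources used here.

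The deposited table holds 1 value per gene and library for 54532 genes, and its header names no unit. The values were read as FPKM made by the authors before they were deposited, since each value multiplied by the gene length in the table and divided by 1 step per library came out whole, within 0.01 reads, for 100% of values above 0. This gave back the reads per gene, 15002922 to 16886945 per library. The library totals implied by the steps were proportional to median-of-ratios size factors, with a constant of 15785100 in every library, so the deposited FPKM were already scaled between libraries. In wild-type 1 the size factor was 0.8589, and in the others 0.977 to 1.057. Gene length is the deposited length of the gene model in bases. The table lists chromosome, start and end, and 99.8% of its gene identifiers were found in a GRCm38 annotation, 98.33% of them with the same coordinates. Genes with near-identical copies are uncertain, since reads with several alignments may have been dropped or split: mt-Co2 had a wild-type mean of 424 FPKM where mt-Co1 had 11000 FPKM. No 2 libraries agreed within sampling noise: the lowest chi-square per gene was 10.7.

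The design set before the data were examined named a test of counts for raw counts, and limma for normalized values. As the file holds FPKM, limma 3.58.1 in R 4.3.3 was used with a variance trend on log2(FPKM + 1) for the 13435 genes with a mean of at least 1 FPKM over all libraries, with genotype as the only term. Adjusted p-values are Benjamini-Hochberg values over these genes, with a threshold of 0.05. Log2 differences are knockout minus wild type on the log2(FPKM + 1) scale, which understates the change of low genes. Padi4 was tested with an exact two-sided permutation test over all splits of the libraries, whose smallest possible p is 0.00794. Fixed with the design were 35 gene lists with 670 genes, for leukocyte types, cytokines, matrix, injury, nephron segments, metabolism and neighbouring tissue. Of these, 34 had a measured gene and were tested with camera at a preset correlation of 0.01, adjusted over the lists. Camera tests whether the genes of a list differ from other genes. Estimated correlation and fry, a rotation test of whether the genes of a list move 1 way on balance, were alternatives. Counts "adjusted over the list alone" use the members of 1 list.

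Genes were named by a rule fixed with the design: Padi4 first, then the genes with the largest change past the threshold. As fewer than 5 passed, the 10 with the smallest p and a symbol other than a clone, model or pseudogene name are given as not past the threshold. Up to 4 members with the smallest p were taken per list. Col1a1, Ly6g, Mpo and Elane were named after their values were seen.

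Alternatives set in advance were upper quartile scaling, limma-voom on the recovered reads, no filter, a mean of at least 5 CPM from the recovered reads, a pseudocount of 0.1, the replicate number as a block, each library left out, other thresholds and the omission of neighbouring-tissue genes. Scaling by median-of-ratios size factors was already in the deposited values. DESeq2 and edgeR were not run, although reads were recovered, and neither was a surrogate variable by sva. Among tests of counts, only limma-voom was run on the recovered reads. On simulated reads with the real means, 5 runs with 200 changed genes each, the comparison recovered 40% of 1.5-fold, 78.4% of 2-fold, 94% of 4-fold and 92% of 8-fold changes over a mean of 13429 genes, and 4.6% of its calls were false. Those simulated genes vary independently, which the genes of these kidneys do not. The changed genes were drawn only from those above a minimum mean of reads, and 200 changes make the adjusted threshold easier to pass. The shares may therefore overstate the power for low genes and for few changes.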

Results

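Messenger RNA was sequenced from mouse kidneys after 10 days of unilateral ureteral obstruction, an operation that ties off 1 ureter and leaves the kidney above it inflamed and scarring. Kidneys of 5 wild-type samples were compared with kidneys of 5 samples labelled as Padi4 knockout. Padi4 is the gene of peptidylarginine deiminase 4, an enzyme that converts arginine to citrulline in histones and takes part in the release of neutrophil extracellular traps. The title of the study names kidney inflammation and fibrosis, so the comparison asked which inflammatory and matrix genes differ between the genotypes in the obstructed kidney. Values were FPKM, and the reads behind them could be recovered. They numbered 15002922 to 16886945 per library, over 20693 to 21606 genes with at least 1 read. No unobstructed kidney was among the samples, so levels before injury are not analysed here. The labels do not say that each library came from a separate animal, and p-values therefore measure the spread between these samples.

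Padi4 itself was close to the detection floor in all 10 kidneys and was not clearly lower in those labelled knockout. The gene lies on the minus strand of chromosome 4, from 140745865 to 140774236 in coordinates that match GRCm38, between Padi6 and Padi3. It measured 0.358 FPKM ± 0.183 (SD, n = 5) in wild-type kidneys and 0.256 FPKM ± 0.164 (SD, n = 5) in those labelled knockout. These means rest on 139 reads and 101 reads in all, with 6 to 47 reads per library. The third library labelled knockout had 43 reads, and the first wild-type library had 6. The difference of -0.11 in mean log2(FPKM + 1) was smaller than the spread between libraries (exact two-sided permutation p = 0.373). The pseudocount shrinks the difference of so low a gene: it was -0.35 with a pseudocount of 0.1 (exact permutation p = 0.397) and -0.49 with limma-voom on the recovered reads (p = 0.341). Which exons were deleted is not given in the sources used here, and transcripts that keep the other exons would still be counted, so this value does not check the genotype labels. "Knockout" below stands for libraries labelled so. Among the other members of the family, Padi2 measured 3.06 FPKM ± 0.8 in wild-type and 2.9 FPKM ± 0.337 in knockout kidneys (SD, n = 5 each). Padi1 and Padi3 stayed below 0.2 FPKM in both group means, and Padi6 had 0 reads in every library.

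No gene passed the threshold between the genotypes. The genes with the smallest p were 3 leukocyte genes with lower values in knockout kidneys and 7 other genes with higher values, and all 10 are named as not past the threshold. S100a9, a subunit of calprotectin that neutrophils carry in abundance, lies on chromosome 3 from 90692632 to 90695721. It measured 6.42 FPKM ± 1.05 in wild-type and 3.35 FPKM ± 0.739 in knockout kidneys (SD, n = 5 each), a log2 difference of -0.78 (SE 0.133, limma adjusted p = 0.976). Itgal, the alpha chain of the leukocyte integrin LFA-1, measured 3.72 FPKM ± 0.492 against 2.1 FPKM ± 0.447, a log2 difference of -0.61. Gzmb, which encodes granzyme B of cytotoxic lymphocytes, measured 1.99 FPKM ± 1.19 against 0.356 FPKM ± 0.257. Its log2 difference was -1.07, and in knockout kidneys it rested on a mean of 8.2 reads per library. The genes with higher values in knockout kidneys were Rab42 at 0.67 on the log2 scale, the mitochondrial leucine tRNA gene mt-Tl2 at 1.60, Tmub1 at 0.42, Tmem203 at 0.46, Slc35f3 at 0.46, Rnf208 at 0.38 and Nr1d1 at 0.69. Nr1d1 encodes REV-ERB alpha, a repressor of the circadian clock. Tmem203 and Rnf208 are neighbours on chromosome 2, and Rab42 lies on chromosome 4 within 10 Mb of Padi4. The mt-Tl2 value is uncertain, since this short gene adjoins mt-Ts2 and mt-Nd5 and reads that span them cannot be assigned to 1 gene.

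**Figure D1:**
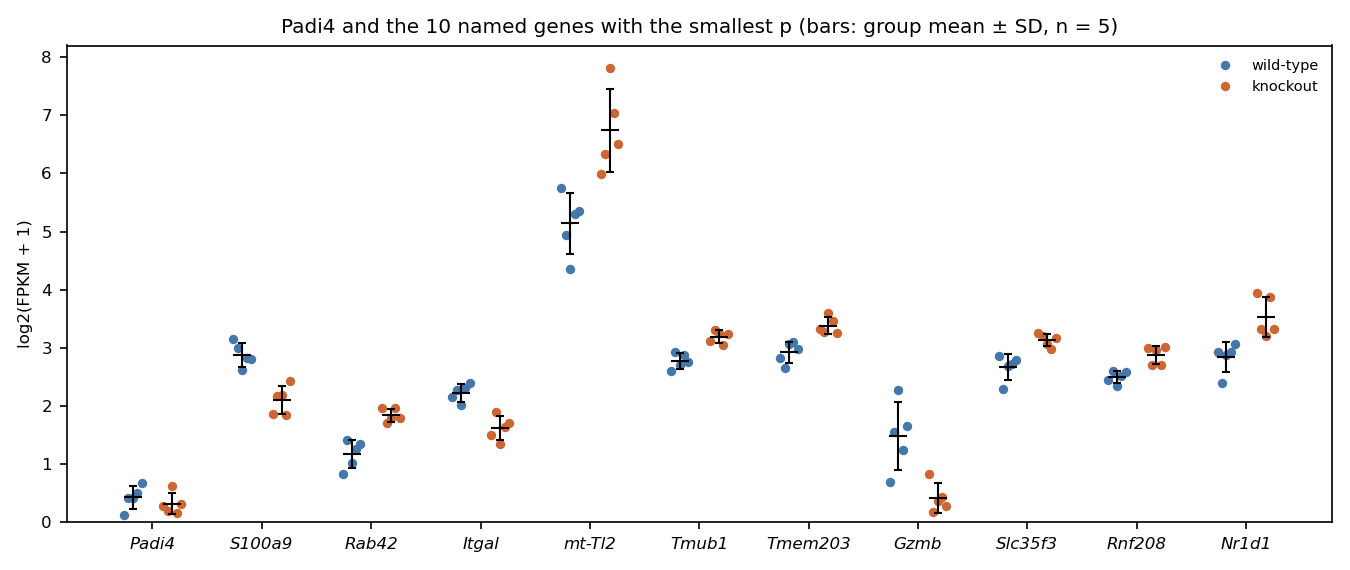
The plot shows log2(FPKM + 1) of Padi4 and of the 10 named genes with the smallest p in each library. Points are libraries, bars are the group mean ± SD with n = 5, and Padi4 overlaps between the groups while S100a9 does not.

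Limma tested 13435 genes with a mean of at least 1 FPKM, and 0 passed a Benjamini-Hochberg adjusted p of 0.05. The smallest adjusted p was 0.976. An unadjusted p under 0.05 was reached by 544 genes, 275 with higher and 269 with lower values in knockout kidneys, where chance alone gives 672. Limma-voom on the recovered reads also called 0 genes, with 529 at an unadjusted p under 0.05. The groups did not overlap for 100 genes, or 0.744% of those tested, and chance gives 0.794%. The unadjusted count depended on single libraries, reaching 916 without wild-type 1 and 1245 without knockout 4, and only 308 without knockout 3.

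T cell and natural killer cell markers had lower values in knockout kidneys for 13 of 13 measured members, with a mean log2 difference of -0.50. The set passed camera with the preset correlation (adjusted p = 2.21e-09) and did not with an estimated correlation (adjusted p = 0.568). No member passed over all genes, and 2 passed when adjusted over the list alone: Gzmb and Nkg7, a cytotoxic granule protein that measured 5.94 FPKM ± 2.75 in wild-type and 2.43 FPKM ± 0.499 in knockout kidneys (SD, n = 5 each). Lck, a kinase of the T cell receptor, and Cd8b1, a chain of CD8, differed by -0.47 and -0.82. The mean of this list was lowest of all in wild-type 1, at -0.50, while the other 4 wild-type libraries were above every knockout library.

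Neutrophil markers had lower values for 5 of 5 measured members, with a mean log2 difference of -0.51. This set also passed with the preset correlation (adjusted p = 2.32e-07), and not with an estimated one (adjusted p = 0.233). No member passed over all genes, and 3 passed when adjusted over the list alone: S100a9, its partner S100a8 at -0.72 and the G-CSF receptor gene Csf3r at -0.29. The other 15 listed neutrophil genes, among them Ly6g, Mpo and Elane, lay below the mean of 1 FPKM. Leukocyte adhesion molecules had lower values for 6 of 8 members, with a mean of -0.16 (adjusted p = 0.0318, and 0.76 with an estimated correlation). Their list-alone calls numbered 2, Itgal and the integrin gene Itga4 at -0.42. The adhesion set lost its call without wild-type 2, 3 or 4 or without knockout 1 or 4, where its adjusted p lay between 0.0661 and 0.181, and was strongest without wild-type 1, at mean log2 fold change -0.244 and adjusted p = 0.000197.

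Macrophage markers showed no such shift. Of 20 measured members, 13 had higher and 7 lower values in knockout kidneys, with a mean of 0.04 (camera adjusted p = 0.786). Trem2, a receptor of lipid-handling macrophages, differed by 0.53 and Adgre1, which encodes F4/80, by -0.35. Without wild-type 1 the list mean was -0.09 (adjusted p = 0.0128), so its direction rested on that library. MHC class II and dendritic cell genes had a mean of -0.04 (adjusted p = 0.412), and B and plasma cell markers -0.21 (adjusted p = 0.142). Mast cell, basophil and eosinophil markers were measured by 1 gene, Kit, at 0.0049 (adjusted p = 0.977). Among cytokines and chemokines 19 of 29 had lower values, with a mean of -0.13 (adjusted p = 0.0548). The smallest p in that list belonged to the inflammatory cytokine genes Il1b, at -0.46, and Il33, at -0.66, and neither passed when adjusted over the list alone. Inflammasome and NF-kB genes had a mean of -0.05 (adjusted p = 0.251), and complement genes 0.05 (adjusted p = 0.674). These immune lists also depended on wild-type 1. Without it the means were -0.23 for MHC class II genes (adjusted p = 4.21e-07), -0.14 for inflammasome genes (adjusted p = 0.000328), -0.20 for cytokines (adjusted p = 9.57e-05), -0.26 for B cell markers (adjusted p = 0.0448) and -0.0624 for complement (adjusted p = 0.0349). The cytokine list also passed without wild-type 3, knockout 3 or knockout 5, at adjusted p = 0.0456, 0.0319 and 0.00307. The MHC class II mean was 0.0411 without wild-type 4 and 0.0133 without wild-type 5, with no call. Over the fits without 1 library, the highest means were -0.0157 for inflammasome genes, -0.0797 for cytokines and -0.119 for B cell markers. All these fits used the preset correlation, where the estimate for MHC class II genes with all libraries was 0.664.

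Proliferation genes had lower values in knockout kidneys for 24 of 25 members. The differences were small, with a mean of -0.15, and the set passed with the preset correlation (adjusted p = 2.32e-07) but not with an estimated one (adjusted p = 0.568). Top2a, the DNA topoisomerase of dividing cells, measured 5.69 FPKM ± 0.757 in wild-type and 4.29 FPKM ± 0.38 in knockout kidneys (SD, n = 5 each), and Mki67, which encodes the proliferation antigen Ki-67, differed by -0.35. Neither passed when adjusted over the list alone. Tubular injury and repair markers had lower values for 21 of 24 members, with a mean of -0.18 (adjusted p = 0.0185, and 0.879 with an estimated correlation). Atf3, Lcn2 (the injury marker NGAL), Sox9 and Krt20 differed by -0.35, -0.50, -0.37 and -0.25. That call was lost without wild-type 2, knockout 1 or knockout 2, at adjusted p = 0.164, 0.191 and 0.121, and was strongest without knockout 5, at mean log2 fold change -0.289 and adjusted p = 2.54e-05. Interferon-stimulated genes had lower values for 18 of 24 members, with a mean of -0.12 (adjusted p = 0.0185, and 0.924 with an estimated correlation). Gbp7, a guanylate-binding protein gene, differed by -0.44. The interferon mean ranged from -0.28 without wild-type 1 to -0.05 without wild-type 2. Its call was lost without wild-type 2, 3, 4 or 5 or knockout 3 or 4, at adjusted p between 0.0619 and 0.337.

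Matrix genes as a set did not pass the threshold between the groups. Of 35 matrix genes 30 had higher values, with a mean of 0.10 that did not pass (adjusted p = 0.0727), and 0 passed over the list alone. Col1a1, the main fibrillar collagen gene, measured 175.6 FPKM ± 49.3 in wild-type and 202.9 FPKM ± 77.5 in knockout kidneys (SD, n = 5 each). Fibroblast and myofibroblast markers had higher values for 13 of 15 members, with a mean of 0.16 that passed with the preset correlation (adjusted p = 0.0185) and not with an estimated one (adjusted p = 0.924). Myl9, a myosin light chain of contractile cells, differed by 0.42 and Des, which encodes desmin, by 0.40. This call rested on a few libraries: the mean was 0.03 without wild-type 1, 0.13 without knockout 2 and 0.09 without knockout 5, with adjusted p = 0.469, 0.0877 and 0.105. Wild-type 1 had list means of -0.59 for matrix and -0.57 for myofibroblast genes, the lowest of all libraries. The matrix mean turned to -0.0373 without wild-type 1 (adjusted p = 0.281). It passed with higher values without wild-type 2, at a mean of 0.21, and without knockout 1, 3 or 4, at 0.15, 0.11 and 0.14 (adjusted p = 2.74e-07, 0.00373, 0.0364 and 0.0433). Matrix proteases and inhibitors had a mean of -0.0037 (adjusted p = 0.801), TGF-beta genes -0.06 (adjusted p = 0.191) and genes of epithelial to mesenchymal transition 0.02 (adjusted p = 0.928). Without wild-type 1 the protease mean was -0.12 (adjusted p = 0.0352) and the TGF-beta mean -0.13 (adjusted p = 0.0133). Without wild-type 2 these means were 0.0875 and 0.0225, with no call.

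Tubule and metabolic gene sets did not pass the threshold with all 10 libraries, and several did without wild-type 1. Means were 0.04 for proximal tubule markers (adjusted p = 0.567), -0.05 for loop, distal tubule and collecting duct markers (adjusted p = 0.412), -0.08 for podocyte markers (adjusted p = 0.0727) and -0.03 for endothelial markers (adjusted p = 0.412). Fatty acid oxidation genes had a mean of 0.09 (adjusted p = 0.0727), with the thiolase gene Acaa2 at 0.30. Tested with the preset correlation, the means without wild-type 1 were 0.35 for proximal tubule (adjusted p = 4.17e-09), 0.25 for fatty acid oxidation (adjusted p = 4.64e-08) and 0.17 for respiratory chain genes (adjusted p = 4.21e-07). They were -0.13 for podocyte markers (adjusted p = 0.00475) and -0.0843 for cell death genes (adjusted p = 0.00538). The loop and collecting duct mean was -0.17 without knockout 1 (adjusted p = 0.00169), and the glycolysis mean -0.14 without wild-type 5 (adjusted p = 0.00794). Further calls, at adjusted p between 0.00662 and 0.0433, came for podocyte markers without wild-type 5 or knockout 3, fatty acid oxidation without knockout 4 or 5, glycolysis without wild-type 4 or knockout 4, and cell death without wild-type 5 or knockout 3 or 5. The proximal tubule mean was below 0 without wild-type 2, 3 or 4 or knockout 1, -0.12 at the lowest, with no call. The respiratory chain mean was -0.0358 without wild-type 2, with no call, and the lowest fatty acid oxidation mean without 1 library was 0.0137. With all libraries the estimated correlation was 0.816 for proximal tubule, 0.576 for fatty acid oxidation and 0.79 for respiratory chain genes. The preset of 0.01 treats such genes as nearly independent, so these small p-values overstate the evidence. Respiratory chain genes had a mean of 0.04 (adjusted p = 0.375), glycolysis and hypoxia genes -0.10 (adjusted p = 0.0727) and cell death genes -0.06 (adjusted p = 0.0535). Antioxidant genes had a mean of -0.02 and a median of 0.02 (adjusted p = 0.786), and the Padi list, with Padi2 alone measured, -0.04 (adjusted p = 0.82). Markers of neighbouring tissue and handling did not pass either: adipose 0.37 (adjusted p = 0.0727), urothelium and smooth muscle 0.14 (adjusted p = 0.412), erythroid -0.21 (adjusted p = 0.266), pancreas and liver 0.28 (adjusted p = 0.202), adrenal 0.09 (adjusted p = 0.699) and immediate early genes -0.11 (adjusted p = 0.0548). No muscle marker reached the mean of 1 FPKM. Knockout 5 had an adipose list mean of 1.79, the highest of all libraries, and without it the adipose difference was -0.0347. Immediate early genes and the pancreas and liver list passed without wild-type 1 (adjusted p = 0.00774 and 0.0257), and erythroid markers without knockout 3 (adjusted p = 0.0465). Adipose markers passed without knockout 4, at a mean of 0.76 (adjusted p = 0.0054), and without wild-type 5 or knockout 3 (adjusted p = 0.00385 and 0.00634). Immediate early genes also passed without wild-type 5, knockout 3 or knockout 5, at adjusted p = 0.00242, 0.0319 and 0.00139.

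**Figure D2:**
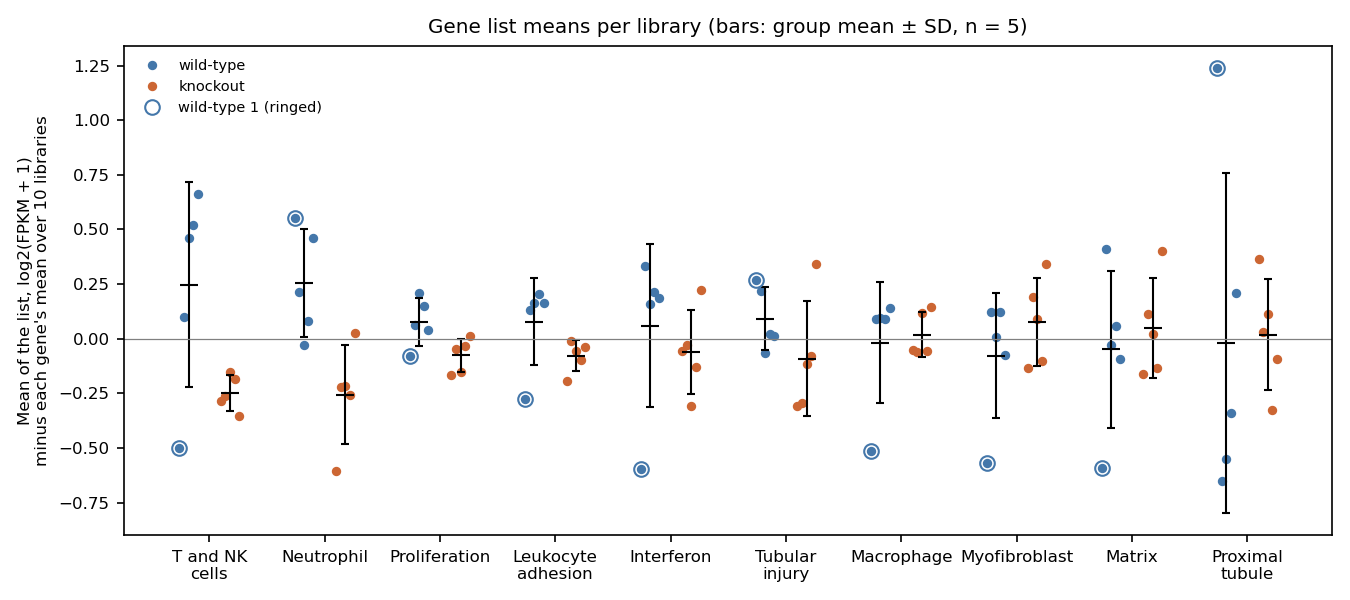
The plot shows the mean of 10 gene lists in each library, as log2(FPKM + 1) minus the mean of each gene over the 10 libraries. Points are libraries, bars are the group mean ± SD with n = 5, and wild-type 1, ringed, lies at -0.50 for T and natural killer cell markers and at 1.24 for proximal tubule markers.

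In all, 7 of 34 lists passed camera with the preset correlation, 6 with lower and 1 with higher values in knockout kidneys. None of the 34 passed with an estimated correlation or with fry. An exact permutation test of the library means also called 0 (smallest adjusted p = 0.54), but it says little: a single list cannot go below an adjusted p of 0.27, and 6 lists at the smallest possible p would be needed. With the preset correlation, the count of 7 became 21 without wild-type 1, 11 without wild-type 5 and 13 without knockout 3. No fit without a library was run with an estimated correlation. Of the 27 lists that did not pass with all libraries, 15 passed without wild-type 1 and 20 without at least 1 library. In the first principal component, which held 33.7% of the variance of the 500 most variable genes, wild-type 1 stood at -22.8 and the other 9 libraries between -6.2 and 11.4, with both genotypes in that range. Mitochondrial genes took 8.11% of its reads and 3.18% to 5.79% in the others.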

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

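Of 110 groups of 5 values examined, 6 held a value far from the other 4, and chance gives about 5.5, or 1 in 20. The 6 all came from wild-type 1, and lists that vary together are not separate flags. Its list means stood apart at -0.567 for myofibroblast markers, -0.275 for leukocyte adhesion molecules, -0.513 for macrophage markers, -0.747 for MHC class II and dendritic cell genes, -0.331 for inflammasome and NF-kB genes and -0.597 for interferon-stimulated genes. In the other 4 wild-type libraries the macrophage means lay between 0.0894 and 0.142 and the interferon means between 0.16 and 0.332. The tests of wild-type 1, of leukocyte markers and of mitochondrial genes given below and in the last part were chosen after the values were seen. Those of other splits of the libraries were set before.

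Wild-type 1 had more proximal tubule RNA and less RNA of macrophage, T cell, interferon and matrix genes than its group, while its neutrophil list mean of 0.554 was the highest of all libraries. A scaling error as the only cause is argued against, since 1 factor alone would move all lists the same way. A scaling error beside another difference is not excluded by this. Its proximal tubule mean was 1.57 above the mean of the other 4 wild-type libraries (SD 0.383) and its matrix mean was -0.678 from theirs (SD 0.224). Its own list means, 1.24 and -0.591, were 1.83 apart. A stricter bound set first, an excess over the other 9 libraries larger than their range of 1.59, was not met at 1.3. Milder tubular injury would lower the injury markers, which were 0.221 higher (SD 0.121). That does not exclude milder injury, since wild-type 2 was nearly as high, at 0.218 against 0.267. The high proximal tubule and low matrix and macrophage means would go with a less damaged kidney, so milder injury stays open. More cortex in the piece would raise podocyte markers, whose mean was -0.261 from that of the other 4 wild-type libraries (SD 0.158). A wrong label or another difference between animals may also account for this library and was not tested. Fewer leukocytes of every type would go against the neutrophil mean.

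Lower T cell and neutrophil markers in knockout kidneys are what a smaller leukocyte infiltrate would give, and chance is the first alternative. Of 100 splits of the 10 libraries into 5 and 5, out of 126 possible, 84 had at least the 7 lists of the real split past the threshold, with a median of 13 and a highest of 27 over the other splits. Chance can therefore not be excluded for the number of lists, and camera with the preset correlation calls lists in most groupings of these libraries. That count does not address the T cell and neutrophil lists by themselves. Exact permutation of their library means gave unadjusted p = 0.0556 for T cell and 0.0159 for neutrophil markers. Adjusted over the lists, these permutation values were 0.63 and 0.54, so chance is not excluded for them either. A loss of every leukocyte type by the same amount is narrowly argued against, since the macrophage difference was 0.0378 (SE 0.132) where T cell markers had -0.495, a gap of -0.533. Minus 2 SE, the macrophage difference was -0.227, just above the bound of -0.248, which is 0.5 times the T cell difference. The bound was set after the values were seen. The T cell list was picked for its low p in these libraries, which may widen the gap. Without wild-type 1 all leukocyte lists but mast cells were lower, yet by unlike amounts, with macrophages at -0.0858 (SE 0.0475), MHC class II at -0.233, B cells at -0.255, neutrophils at -0.436 and T cells at -0.683 (SE 0.125), so a general loss of unequal size stays open. Length and GC bias is argued against too, with a T cell list mean of -0.518 after correction, and a genotype effect on these cells stays open as a hypothesis.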

How the results depend on the processing

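Alternatives with read totals or TMM as scaling, a residual principal component, a length and GC correction, permutation of list means, a list minimum and pairs of omitted libraries were chosen after seeing the data. No gene passed in any of the 25 other settings. An adjusted p of 0.1 and a minimum of 2-fold only change the threshold of the main fit, whose smallest adjusted p was 0.976. Their 0 was therefore fixed by the main fit. Leaving out each library gave 0 genes each time, and a Padi4 difference between -0.19 and -0.05. That difference was -0.35 with a pseudocount of 0.1 and -0.49 with limma-voom, and it did not pass in any fit. The 10 named genes kept their direction in 217 of 217 other values, and 0 of these passed. They were picked for the smallest p in these same libraries, so a change of direction was unlikely from the start. The count is therefore not separate support. The T cell, neutrophil and proliferation lists were picked as those that passed without each library. They were below 0 and passed in 60 of 60 values from the 20 fits that can move a list mean. Those 20 include the fits without each library, so part of this count was fixed by the choice. The 20 fits also share these libraries and the preset correlation, so the count is not separate support. These lists did not pass with the estimated correlation, fry or permutation. From 7 lists, the count became 15 at an adjusted p of 0.1, 14 with the length and GC correction, and 0 with the estimated correlation, with fry and with permutation, where a single list cannot go below an adjusted p of 0.27. It was 10 with lists of at least 3 measured genes, a minimum tried after first results were seen and set aside because the design names none. Leaving out 1 library gave 5 to 21 lists. Without wild-type 1 and knockout 5 there were 22, and without wild-type 1 and 5, the libraries with the highest mitochondrial share, 24. The cause was not tested.

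For lists past the threshold in either fit, directions turned only where wild-type 1 was left out, and 47 other values of lists changed sign with no call in either. Without wild-type 1 and knockout 5 the means were -0.13 for matrix, -0.0321 for myofibroblast, -0.12 for macrophage, -0.13 for complement and -0.29 for urothelium lists. Without wild-type 1 and 5 they were -0.0966, -0.0060 and -0.0733 for matrix, myofibroblast and macrophage lists, -0.32 for urothelium and 0.16 for antioxidant genes. Without wild-type 1 alone, the macrophage and complement means were -0.0858 and -0.0624, the lowest of the fits without 1 library, whose highest were 0.0781 and 0.142. The number of genes at an unadjusted p under 0.05 was 1096 of 27780 with no filter, where chance gives 1389 on average, and 819 of 13435 with the residual component. With the replicate number as a block, 12 lists and 0 genes passed. Same-numbered libraries correlated at 0.306, 0.111, -0.124, -0.344 and -0.04, which gave no clear sign that the numbers pair the samples. For replicates 1 and 2 the same-numbered library was the best partner, and for 3, 4 and 5 it was not, so pairing is not excluded. DESeq2, edgeR and sva were not run. Padi4 rests on 6 to 47 reads per library, and the power to detect a partial loss at that depth was not tested.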

Other observations

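The tests in this part were chosen after the values were seen, except those of other splits. With 0 genes past the threshold in the real split, all 100 splits call as many by construction, which decides nothing, and the highest of the others was 2. At least its 544 genes at an unadjusted p under 0.05 were found in 50 splits, and the highest of the others had 2842. Chance can therefore not be excluded for the unadjusted count.

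Mitochondrial genes in 2 stretches had higher values in knockout kidneys. The first stretch holds mt-Tg and mt-Nd3, from 9391 to 9806 of the mitochondrial genome, and the second mt-Th, mt-Ts2 and mt-Tl2, from 11546 to 11741. Their log2 differences were 1.42, 1.55, 1.26, 1.57 and 1.60, and none passed the adjusted threshold. These 5 genes were picked because they were higher. The 12 other mitochondrial protein-coding genes had a mean of -0.0918 (SE 0.454) and 12 other mitochondrial tRNA genes 0.147 (SE 0.381), where the 4 tRNA genes had 1.46. The mitochondrial share of all reads differed by -0.143 on the log2 scale (SE 0.272), which argues against more mitochondrial RNA overall; this measure replaced the 12-gene mean after both were seen, and the 12-gene mean alone could not tell. The spread between libraries is too wide to exclude better recovery of short transcripts. The gene mt-Tr, which adjoins mt-Nd3, had 0.837 and is counted with the other tRNA genes. In wild-type kidneys mt-Nd3 had a mean of 69.3 FPKM where mt-Co1 had 11000 FPKM, so reads with several alignments may have been lost there. Such a loss, reads spanning neighbouring genes, mitochondrial DNA variants between the mouse lines and transcript processing stay open, and were not tested.

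Strain DNA carried along with the deleted gene may change nearby genes in knockout mice. Of 219 tested genes within 10 Mb of Padi4, 11 had an unadjusted p under 0.05, or 5.02%, against 4.03% of other genes (one-sided Fisher's exact p = 0.275). This gave no clear sign of an excess, but a test of the share cannot exclude an effect on single genes. Rab42, also among the 10 named genes, lies within this window, on chromosome 4 from 132302197 to 132303385. Its groups did not overlap, with 0.775 to 1.67 FPKM in wild-type and 2.25 to 2.9 FPKM in knockout kidneys. Strain DNA therefore stays open for Rab42, and was not tested gene by gene.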
